A study of Mus musculus with 4 samples.

How the data were processed

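Total RNA from normal ureter and from ureter tumors of mice was measured on one-colour Affymetrix Mouse Genome 430 2.0 arrays, with 2 arrays per group. Per the labels' protocols, ureter epithelium of mice aged 6 to 8 weeks was isolated, RNA was extracted with Trizol and purified on a column, and biotinylated cRNA was made from 6 ug of total RNA. The authors deposited a table of linear signal intensity per probe set, made with MAS5 per the submitters' processing notes. The version of MAS5, the detection calls and any filter are not given in the sources used here. On each array the mean after trimming 2% of probe sets at each end was 500, so the deposited intensity values had been scaled to one target. Such scaling makes every signal relative to the rest of its array.

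The table held 45101 probe sets, of which 64 were controls and were left out of the tests. Gene symbols came from the platform annotation of the chip, and the symbol was updated through a newer gene table for 34741 of the 34945 probe sets with 1 gene symbol. A further 932 probe sets had several symbols and 9160 had no symbol here, and none of these was named as a gene. The deposited signal was transformed as log2(signal + 16), which understates the change of dim genes, and fold changes are on that scale. Each of 18193 genes was read from its single-gene probe set with the highest mean, and the 13046 genes with a mean at or above the 40th percentile of all probe sets other than controls, a signal of 54.65, were tested. Of these, 1477 were read by a probe set whose name marks probes shared between transcripts. Among 90 named genes with several bright probe sets, 11 had a probe set that pointed the other way, and among the 28 of these that passed the test 1 did.

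Tumor and normal ureter were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior variance. The test is two-sided and used Benjamini-Hochberg adjustment over the genes tested, with 0.05 as the threshold. There were 2 residual degrees of freedom and 2.11 prior ones. With 2 against 2 samples an exact permutation test cannot go below p = 0.333, so no single gene was tested that way. Gene lists were fixed before the data were examined. There were 41 lists with 923 genes, of which 853 were measured, and the 40 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. The median log2 difference over all genes tested was 0.03.

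Named genes followed a rule that was also fixed before the data were examined. It takes the 15 genes with the largest rise and the 15 with the largest fall among those past the threshold whose tumor arrays both lay on one side of both normal arrays. It adds Ncstn, Notch1, Notch2, Notch3, Jag1, Hes1, Hey1 and the listed phosphatases whatever their result. From each list described it takes up to 4 genes with the smallest unadjusted p and, from lists of cell types, the brightest gene. Genes named outside this rule stand in the closing part and were chosen after their values were seen.

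The procedure was tested on simulated data with 200 changed genes among 13046 in each of 10 runs. Of genes changed by 1, 2 and 4 log2 units, 0%, 0.896% and 26.7% were called, with mean estimates of 0.975, 1.98 and 4.05. False calls made up 3.19% of all calls. A shifted list was called in 10 of 10 runs, and 0 of 390 unshifted lists were called. The simulated genes varied independently and with the same SD in both groups. The rates of false calls therefore do not carry over to lists of correlated genes or to groups of unequal spread, as in these data. The share of changed genes that is called depends, through the adjustment, on how many genes change, so it need not carry over either.

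The alternatives were pseudocounts of 1 and 64, quantile normalization, centring on the median, no filter and a filter at the 60th percentile, the mean of a gene's probe sets and every probe set, no intensity trend and a robust one, the replicate number as a block, a rule of 2-fold at an unadjusted p under 0.05, and leaving out each array in turn. An array left out leaves its group with 1 array, which is then assumed to vary like the arrays of the other group. Figures were drawn with matplotlib 3.10.9.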

Results

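Gene expression was measured in ureter tissue of C57Bl/6 mice aged 6 to 8 weeks, described in the labels' protocols as isolated epithelium. There were 2 normal ureter samples and 2 ureter tumor samples, each on 1 Affymetrix Mouse Genome 430 2.0 array. The study addressed the part that Notch signaling plays in cancer of the urothelium, the epithelium that lines the urinary tract. The labels describe mice with a doxycycline-inducible Cre recombinase and conditional alleles of Ncstn, given doxycycline for 1 week from the age of 3 weeks. Ncstn encodes nicastrin, a subunit of the gamma-secretase complex that releases the intracellular domain of Notch receptors. The same treatment text stands on all 4 samples, and the genotype of each sample is not given in the sources used here. The deposited values were MAS5 signals of 45101 probe sets, with a trimmed mean of 500 on each array. The median signal was 106.7 and 102.9 on the normal arrays and 85.03 and 94.2 on the tumor arrays, and the number of arrays limits the precision of every comparison. The labels call the samples biological replicates without naming the animals, so the limma p-values measure the spread between these samples. The camera p-values at the preset correlation do not measure that spread. They set list genes against other genes as if nearly independent, although estimated correlations reached 0.964 in the mast cell list.

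The normal arrays resembled each other more than the tumor arrays did. Over the 13046 genes tested, Pearson's r across genes was 0.976 between the normal arrays and 0.786 between the tumor arrays, against 0.769 to 0.827 between a normal and a tumor array. These correlations run across genes, which are not independent replicates. Between the tumor arrays 1111 genes differed at least 4-fold, and between the normal arrays 49 did. The ratio of 3' to 5' signal for Gapdh, a measure of RNA integrity, was 0.92 and 0.923 on the normal arrays and 1.51 and 1.44 on the tumor arrays. For Actb the same ratio was 2.9 and 2.82 against 2.47 and 2.63.

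The targeted gene, Ncstn (1418570_at), gave a signal of 99.0 and 66.2 on the normal arrays and 81.6 and 131 on the tumor arrays. The difference on the log2 scale was 0.30 (SE 0.42, n = 2 per group, limma adjusted p = 0.725). Averaging the probe sets of Ncstn turned its difference to -0.11, since the other probe set, 1444532_at, was lower in the tumors by this measure at -0.53. The deleted part of the gene is not given in the sources used here, so Ncstn checked neither the deletion nor the labels. Among the 5 gamma-secretase genes tested, 0 passed, and Aph1a and Aph1b had differences of 1.12 (adjusted p = 0.077) and -1.12 (adjusted p = 0.207), although a dimmer probe set of Aph1a gave -0.26. Adjusted over the list alone, 1 gene was higher and 0 were lower.

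Notch pathway genes did not pass the limma test as single genes or the camera test as groups. The fry test for changes in either direction passed the receptor, gamma-secretase and target lists (adjusted p = 0.00395, 0.00397 and 0.015), among 33 of the 40 lists. In the simulation, where 200 genes were changed, limma called 0.896% of genes changed by 2 log2 units. That share need not hold for these data, but a single gene short of the threshold may still have changed. Of 22 receptors, ligands and regulators 0 passed, and of 9 target genes 0 passed, and adjusted over the list alone 0 and 2 did, the latter being 1 higher and 1 lower. Nrarp, a feedback inhibitor that Notch induces, had the largest difference of the named target genes at -2.94 (SE 0.41, n = 2 per group, limma adjusted p = 0.069), from a signal of 3557 ± 1600 to 433 ± 113 (SD, n = 2). The transcriptional repressor Hey1 had a difference of -1.12 (adjusted p = 0.165), Hes1 -0.14 (adjusted p = 0.884) and Myc, a growth regulator, 1.40 (adjusted p = 0.0843). The receptors Notch1, Notch2 and Notch3 had differences of -0.34, 0.65 and -0.19, and the ligand Jag1 -0.02, with adjusted p-values from 0.308 to 0.976. Mfng, a glycosyltransferase that modifies Notch receptors, had a difference of -1.20 (adjusted p = 0.138), and the Deltex genes Dtx2 and Dtx3 had differences of -0.95 and 0.95. The camera test gave adjusted p = 0.672 for the receptor list, 0.845 for the gamma-secretase list and 0.906 for the target list. In the gamma-secretase list the median difference was -0.05 while the mean was 0.03 and the test pointed up. Without tumor replicate 1, the test of the receptor and gamma-secretase lists turned direction, with medians of 0.05 and -0.28, and without tumor replicate 2 that of the target list did, with a median of 0.22.

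Dual-specificity phosphatases, which switch off MAP kinases, gave 0 of 12 genes past the test over all genes. Adjusted over the list alone, 2 were higher and 2 lower. Those with the smallest p-values were Dusp4 with a difference of -1.43 (SE 0.23, limma adjusted p = 0.0813), Dusp14 with 1.97 (SE 0.36, adjusted p = 0.0996), Dusp5 with 1.95 (SE 0.44, adjusted p = 0.128) and Dusp16 with -0.79 (SE 0.20, adjusted p = 0.148), with n = 2 per group. Dusp6, a feedback phosphatase of ERK, had a difference of 1.61 (adjusted p = 0.181) and Dusp7 one of 1.02 (adjusted p = 0.167). Dusp1, Dusp2, Dusp3 and Dusp10 had differences of -0.11, 0.65, 0.17 and 0.30, and Dusp8 and Dusp9 had differences of -0.10 and -0.16, or 0.09 and 0.04 under quantile normalization. Each of these genes lay on opposite sides of the normal mean in the tumor arrays. The camera test of the list gave adjusted p = 0.454 with a median of 0.24. Genes that respond to ERK shifted upward as a list (median 0.55, camera adjusted p = 0.0197, and adjusted p = 0.657 with an estimated correlation), as did immediate early genes (median 0.50, camera adjusted p = 0.0273, and adjusted p = 0.657 with an estimated correlation). In the ERK list 1 of 12 genes rose and 11 did not pass, and adjusted over the list alone 3 were higher. In the immediate early list 1 of 18 rose, 17 did not pass, and adjusted over the list alone 1 was higher. Ier3, an early response gene, rose by 2.18 on the log2 scale (SE 0.18, limma adjusted p = 0.0408) and Egr2, a zinc-finger transcription factor, rose by 2.90 (SE 0.28, adjusted p = 0.0435). Hbegf, a ligand of the EGF receptor, had a difference of 1.65 (adjusted p = 0.0657), and Jun and Atf3 had differences of 0.96 and 1.13 (adjusted p = 0.136 and 0.137). Without tumor replicate 1 the medians were 0.51 and 0.12 and neither list passed, with adjusted p = 0.0993 and 0.567, and without normal replicate 1 the immediate early list missed the threshold with adjusted p = 0.0527.

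**Figure D1:**
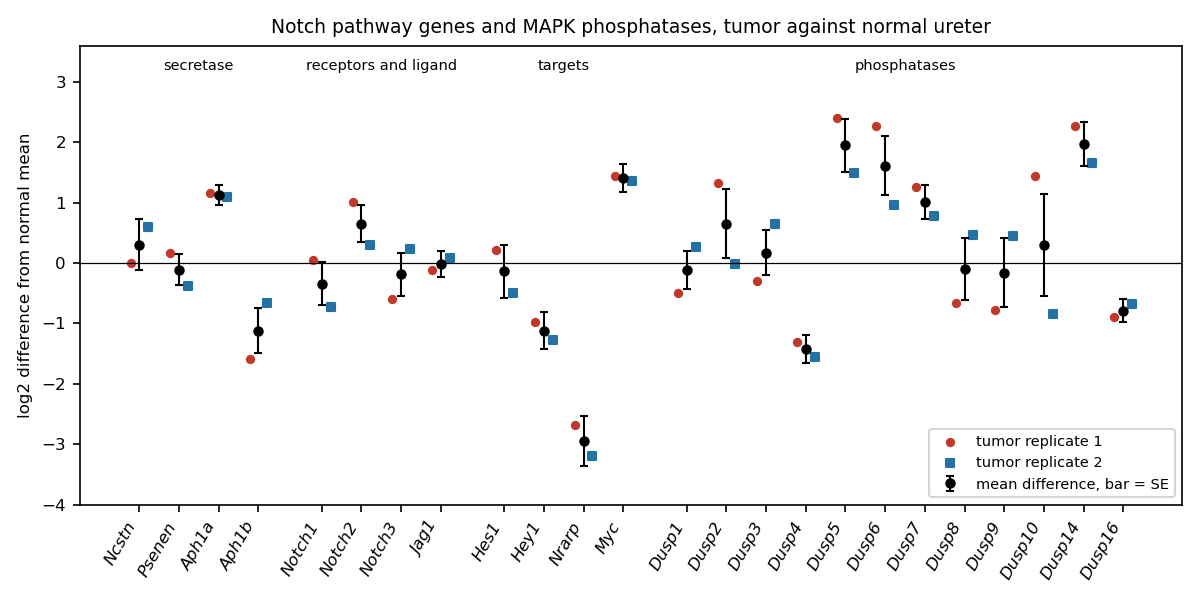
Log2 differences in signal between tumor and normal ureter for genes of the Notch pathway and dual-specificity phosphatases. The horizontal axis names the genes and the vertical axis gives the log2 difference from the normal mean. Black points are the mean difference with its SE from limma (n = 2 per group), and red circles and blue squares are tumor replicates 1 and 2. Nrarp lies lowest at -2.94 and Dusp14 highest at 1.97, and none of these genes passed the test.

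In the camera test at the preset correlation of 0.01, lists of umbrella cell, fat cell and smooth muscle genes shifted downward in the tumors, and lists of plasma cell and macrophage genes shifted upward. With an estimated correlation none of these lists passed (camera adjusted p = 0.657 each), and in each of them most genes did not pass the limma test. That form of camera rests on the 2 residual degrees of freedom, so it had little power here. The ERK and skeletal muscle lists also lost their calls, with estimated correlations of -0.0758 and 0.00803, below the preset 0.01. A lost call therefore does not show that correlation between genes made the shift. The limma test called 187 of 13046 genes, of which 64 rose and 123 fell, each by at least 2-fold. The smallest adjusted p was 0.00863. At an unadjusted p under 0.05 there were 2802 genes, 1382 higher and 1420 lower, where 652 would come by chance. In 3837 genes both tumor arrays lay above both normal arrays and in 3609 both lay below, together 57.1% of the genes where chance gives 33.3%. Leaving out normal replicate 1 or normal replicate 2 left 0 genes past the limma test, with 884 and 889 at an unadjusted p under 0.05, and this ended the call of all 56 called genes named here. The differences themselves moved little for Igha, at 7.14 without normal replicate 1 and 7.20 without normal replicate 2. The same held for Ucp1, at -10.13 and -9.995, while Alb moved more, at -6.05 and -4.52. Without the intensity trend 2 genes passed, with 2739 at an unadjusted p under 0.05, and 2 of the 56 calls were kept. Leaving out tumor replicate 1 gave 4298 genes and leaving out tumor replicate 2 gave 5502, and each of these sets held all 187.

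Among the genes past the test, the largest rises were in immunoglobulin genes, which plasma cells transcribe. Igha (1425763_x_at), the heavy chain of IgA, rose by 7.17 on the log2 scale (SE 0.17, n = 2 per group, limma adjusted p = 0.00863), from a signal of 453 ± 13.7 to 67425 ± 2290 (SD, n = 2). Jchain, which joins IgA units, rose 39.7-fold to 42412 ± 6660 (adjusted p = 0.0288). The light chain genes Igkv8-30, Iglv1, Igk, Igkv9-120 and Igkv15-103 rose by 6.83, 6.34, 5.22, 4.50 and 4.30 on the log2 scale. Several of these probe sets have probes shared between similar transcripts, so single immunoglobulin genes are uncertain. Of the other genes past the test with the largest rises, Olfm4, a secreted glycoprotein, rose by 4.86 (SE 0.34), Inhba, a subunit of activin A, rose by 4.57 (SE 0.34) and Frzb, a secreted Wnt antagonist, rose by 4.57 (SE 0.29). Slc26a4, an anion exchanger, rose by 4.07, the G protein-coupled receptor Gpr176 by 4.01, the tight junction gene Cldn3 by 3.74, the macrophage receptor Trem2 by 3.61 and the actin-binding gene Tagln2 by 3.50. Tagln2 was read from 1439407_x_at, and its other bright probe set, 1426529_a_at, gave 1.23. The normal means of Igk, Olfm4, Inhba, Igkv9-120, Gpr176 and Trem2 lay under the filter limit of 54.65, so the size and order of these rises depend on the pseudocount, and Gpr176 rose by 5.12 with a pseudocount of 1 and 2.70 with 64. The call of Igk ended with a pseudocount of 1 (adjusted p = 0.0509). The adjusted p-values of these 13 genes other than Igha and Jchain ran from 0.0369 to 0.0487, and these calls ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

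Plasma cell, macrophage and antigen-presenting cell genes shifted upward as lists, on both tumor arrays. The macrophage and monocyte list had a median of 2.06 (2.27 and 1.89 on tumor replicates 1 and 2), and the camera test gave adjusted p = 2.65e-14, and adjusted p = 0.657 with an estimated correlation. Of its 23 genes 4 rose and 19 did not pass, while adjusted over the list alone 22 were higher. C1qb, a complement component, rose by 2.65 on the log2 scale (SE 0.20, n = 2 per group, limma adjusted p = 0.0402), and Ms4a7, Mpeg1 and the receptor Csf1r rose by 2.63, 2.26 and 1.96 (adjusted p = 0.0425 each). Lyz1, the brightest member, had a difference of 1.11 (adjusted p = 0.207). The class 2 and dendritic list had a median of 1.93 (2.19 and 1.48 on tumor replicates 1 and 2, camera adjusted p = 6.4e-07, and adjusted p = 0.657 with an estimated correlation), with 1 of 11 genes past the test and 7 higher when adjusted over the list alone. Cd74, the invariant chain, rose by 2.44 (SE 0.20, adjusted p = 0.0408), and H2-Eb1 and H2-Aa had differences of 2.03 and 1.70 (adjusted p = 0.0639 and 0.0709). The B and plasma cell list had a median of 1.70 (2.56 and 1.05 on tumor replicates 1 and 2, camera adjusted p = 0.000526, and adjusted p = 0.657 with an estimated correlation), and without tumor replicate 1 its adjusted p was 0.0457. Of its 15 genes Jchain alone rose, 14 did not pass, and adjusted over the list alone 4 were higher and 1 lower. Mzb1 and Pou2af1, expressed in plasma and B cells, had differences of 4.55 and 5.02 (adjusted p = 0.0521 and 0.0777), Ighm, the brightest member, 3.32 and the B cell factor Ebf1, which is also expressed in fat, -1.56. The gene calls ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

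Neutrophil, cytokine, T and NK cell and mast cell lists had higher medians on tumor replicate 1 than on tumor replicate 2. The neutrophil list shifted upward with a median of 1.89 (3.05 and 1.35 on tumor replicates 1 and 2, camera adjusted p = 0.00137, and adjusted p = 0.657 with an estimated correlation). Of its 12 genes 0 passed and adjusted over the list alone 1 was higher. Il1b, an inflammatory cytokine, had a difference of 3.09 (SE 0.43, n = 2 per group, limma adjusted p = 0.0686), S100a9 one of 3.92 (5.49 and 2.35 on tumor replicates 1 and 2), Ltf one of 6.43 (8.90 and 3.96) and Lcn2, the brightest member and also a transcript of injured kidney, one of 5.34 (3.199 and 7.491). Cytokines and chemokines shifted upward with a median of 2.15 (2.47 and 1.08 on tumor replicates 1 and 2, camera adjusted p = 5.09e-05, and adjusted p = 0.657 with an estimated correlation). Of 29 genes 2 rose and 27 did not pass, and adjusted over the list alone 7 were higher and 1 lower. The chemokines Cxcl1 and Cxcl16 rose by 2.57 and 2.33 on the log2 scale (adjusted p = 0.0487 and 0.0425), and Cxcl9 had a difference of -1.79 (adjusted p = 0.0713). The T and NK cell list shifted upward with a median of 1.00 (camera adjusted p = 0.0465, and adjusted p = 0.713 with an estimated correlation), with 0 of 18 genes past the test over all genes and 0 when adjusted over the list alone. Without tumor replicate 1 its median was 0.15 and adjusted p = 0.867. Il7r had a difference of 2.67 (3.68 and 1.65 on tumor replicates 1 and 2), and Gzma, the brightest member, had a signal of 15262 on tumor replicate 1 and 69.4 on tumor replicate 2, beside 161 and 147 on the normal arrays. The mast cell list had a median of 1.85 (camera adjusted p = 0.105), 4.70 on tumor replicate 1 and -0.52 on tumor replicate 2, with 0 of 9 genes past the test and 0 when adjusted over the list alone. Without tumor replicate 2 it passed, with adjusted p = 2.29e-09. Mcpt2, a mast cell protease, had a signal of 52197 on tumor replicate 1 and 33.7 on tumor replicate 2, beside 2.21 and 2.43 on the normal arrays. The calls of Cxcl1 and Cxcl16 ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

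**Figure D2:**
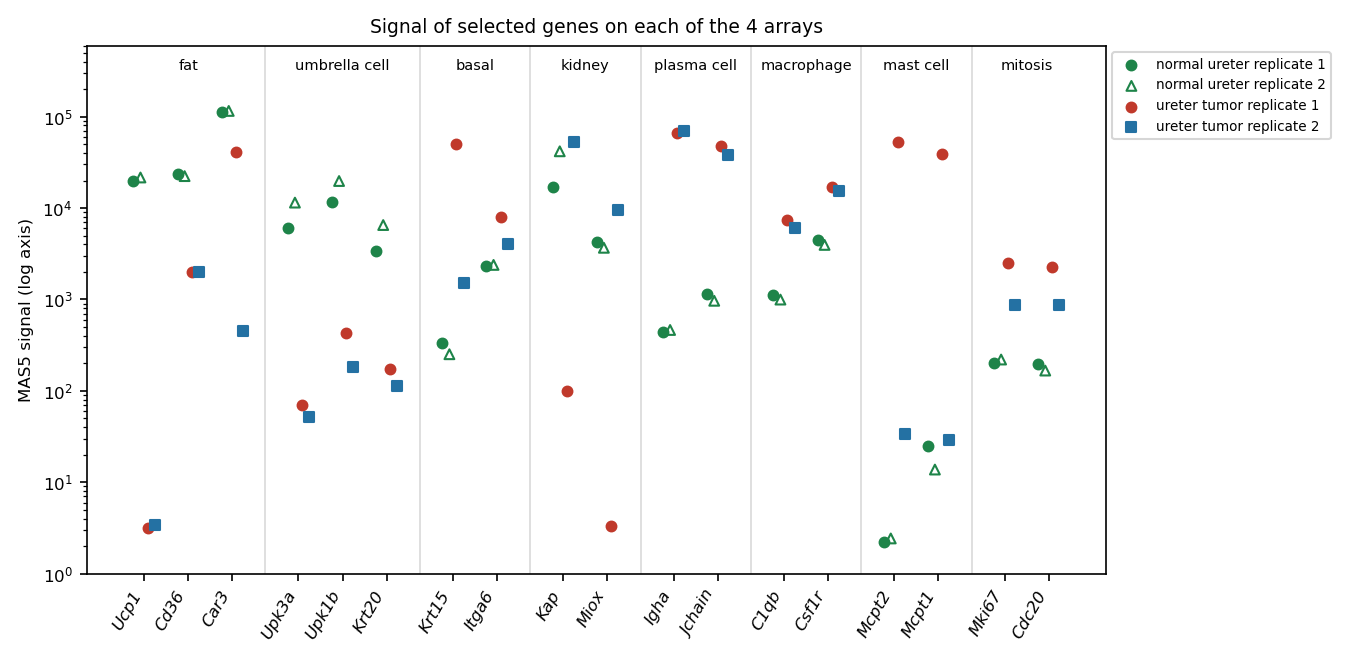
MAS5 signal, on a log axis, of 18 genes grouped by the cell type or process they mark. Green symbols are the normal ureter arrays, red circles tumor replicate 1 and blue squares tumor replicate 2, with 1 point per array. Ucp1 and Upk3a lay far lower on both tumor arrays, and Igha and Jchain far higher. Krt15 and Mcpt2 were high on tumor replicate 1 (50290 and 52197), and Kap was at 101 on tumor replicate 1 and 52269 on tumor replicate 2.

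Mitosis genes shifted upward as a list, with a median of 1.72 (2.06 and 1.30 on tumor replicates 1 and 2, camera adjusted p = 3.79e-08, and adjusted p = 0.657 with an estimated correlation). Of 23 genes 0 passed over all genes and 16 were higher when adjusted over the list alone, and 22 lay above both normal arrays on both tumor arrays. Cdc20 had a difference of 2.87 (SE 0.53, n = 2 per group, limma adjusted p = 0.0986), Birc5, which guides chromosome segregation, one of 2.91, the proliferation marker Mki67 one of 2.71 and the mitotic kinase Plk1 one of 2.22. DNA replication genes shifted upward with a median of 0.72 (camera adjusted p = 5.22e-05, and adjusted p = 0.657 with an estimated correlation), with 0 of 26 genes past the test and 0 when adjusted over the list alone. Without tumor replicate 1 their median was 0.30 and adjusted p = 0.0993. Rrm2, a subunit of ribonucleotide reductase, had a difference of 2.74 (adjusted p = 0.08) and Mcm5, part of the replicative helicase, one of 1.90 (adjusted p = 0.128). The p53 target list had a median of 0.25 and did not pass (camera adjusted p = 0.233), with 0 of 20 genes past the test over all genes or when adjusted over the list alone.

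Umbrella cell genes, which mark the differentiated surface layer of the urothelium, shifted downward in the tumors as a list. The list fell with a median of -2.41 (-2.02 and -2.91 on tumor replicates 1 and 2, camera adjusted p = 6.04e-07, and adjusted p = 0.657 with an estimated correlation). Of 20 genes 6 fell and 14 did not pass, and adjusted over the list alone 10 were lower. Upk3a (1449104_at), a uroplakin of the apical plaques, fell by 6.76 on the log2 scale (SE 0.39, n = 2 per group, limma adjusted p = 0.0369), from a signal of 8725 ± 3870 to 61.1 ± 12.4 (SD, n = 2). The uroplakin Upk1b fell by 5.66 (SE 0.52, adjusted p = 0.0425), the keratin Krt20 fell by 4.93 (SE 0.42, adjusted p = 0.042) and the sorting nexin Snx31 fell by 4.50 (SE 0.33, adjusted p = 0.0402). Pparg, a nuclear receptor of both urothelial and fat cell differentiation, fell by 4.85 (SE 0.44, adjusted p = 0.0425). Krt7, the brightest member, had a difference of -0.67 (adjusted p = 0.577). The gene calls ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

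Basal epithelial genes had a median of 1.23 and did not pass as a list (camera adjusted p = 0.0577), with medians of 2.03 on tumor replicate 1 and 0.14 on tumor replicate 2. Of 16 genes 0 passed, and adjusted over the list alone 1 was higher and 1 lower. Without tumor replicate 2 the list passed, with adjusted p = 7.31e-09. Krt15, a keratin of basal cells, had a signal of 50290 on tumor replicate 1 and 1523 on tumor replicate 2, beside 336 and 251 on the normal arrays (adjusted p = 0.233). The cadherin Cdh3 and the integrin Itga6 had differences of 1.89 and 1.27 (adjusted p = 0.0831 and 0.177), and the secreted ligand Shh, made by basal urothelial cells, one of -4.67 (SE 0.69, n = 2 per group, limma adjusted p = 0.0729). Squamous and cornification genes had a median of 0.15, a mean of 0.56 and a test that pointed down (camera adjusted p = 0.845), with 0 of 15 genes past the test over all genes or when adjusted over the list alone, and the test pointed up without tumor replicate 2, with a median of -0.07. Krt4, a squamous keratin, had a signal of 16802 on tumor replicate 1 and 201 on tumor replicate 2, beside 49.6 and 21.3 on the normal arrays, while Ivl, a precursor of the cornified envelope, had a difference of -3.99 (adjusted p = 0.167). Epithelial junction genes shifted upward with a median of 0.58 (0.73 and 0.29 on tumor replicates 1 and 2, camera adjusted p = 0.0105, and adjusted p = 0.657 with an estimated correlation), and without tumor replicate 1 the adjusted p was 0.047. Of 26 genes Cldn3 alone rose, 25 did not pass, and adjusted over the list alone 3 were higher. Epcam, an epithelial adhesion molecule, had a difference of 1.82 and Cdh1, E-cadherin, one of 0.85 (adjusted p = 0.0961 and 0.174). The call of Cldn3 ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

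Genes of matrix breakdown and mesenchymal transition shifted upward. The protease list had a median of 1.66 (2.04 and 1.27 on tumor replicates 1 and 2, camera adjusted p = 3.42e-06, and adjusted p = 0.657 with an estimated correlation). Of 20 genes Adamts1, a secreted metalloprotease, alone rose, by 2.17 on the log2 scale (SE 0.22, n = 2 per group, limma adjusted p = 0.0448), 19 did not pass, and adjusted over the list alone 6 were higher. Mmp12, the macrophage elastase, and Adamts4 had differences of 4.87 and 3.83 (adjusted p = 0.0734 and 0.0566). The mesenchymal transition list had a median of 0.63 (1.01 and 0.35 on tumor replicates 1 and 2, camera adjusted p = 0.0434, and adjusted p = 0.657 with an estimated correlation). Of 22 genes 1 rose and 21 did not pass, and adjusted over the list alone 6 were higher. That gene, Itgb6, is an epithelial integrin subunit that activates TGF-beta, and it rose by 1.95 (SE 0.21, adjusted p = 0.0496), with -0.34 on a dimmer probe set. Tgfbr1, Itgav and Fn1 had differences of 1.45, 1.55 and 1.59 (adjusted p = 0.0526, 0.0607 and 0.126). Without tumor replicate 1 the mesenchymal transition list missed the threshold with adjusted p = 0.212, and without normal replicate 2 with adjusted p = 0.0836. The fibroblast and collagen list had a median of 0.74 (1.01 and -0.02 on tumor replicates 1 and 2) and did not pass (camera adjusted p = 0.219), with 0 of 25 genes past the test over all genes or when adjusted over the list alone. It passed without tumor replicate 2 with adjusted p = 2.05e-05 and without normal replicate 1 with adjusted p = 0.0496. The gene calls of Adamts1 and Itgb6 ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

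Fat cell genes were lower on both tumor arrays. The adipocyte list had a median of -4.06 (-3.28 and -5.08 on tumor replicates 1 and 2, camera adjusted p = 1.27e-13, and adjusted p = 0.657 with an estimated correlation). All 17 of its genes lay below both normal arrays on both tumor arrays, 6 fell, 11 did not pass, and adjusted over the list alone 15 were lower. Ucp1 (1418197_at), the uncoupling protein of brown fat, fell by 10.06 on the log2 scale (SE 0.20, n = 2 per group, limma adjusted p = 0.00863), from a signal of 20620 ± 1360 to 3.28 ± 0.182 (SD, n = 2). The tumor signal of Ucp1 lay under the filter limit of 54.65, so the size depends on the pseudocount, and it was -12.23 with a pseudocount of 1 and -8.26 with 64. Cox8b, a respiratory chain subunit of muscle and brown fat, fell by 8.80 (SE 0.54, adjusted p = 0.0369), and the fatty acid carrier Cd36 and the lipase Pnpla2 fell by 3.52 and 3.50 (adjusted p = 0.0369 each). The triglyceride enzyme Dgat2 fell from a signal of 10802 ± 325 to 669 ± 142 (SD, n = 2, adjusted p = 0.0369). Car3, the brightest member, had a signal of 41019 on tumor replicate 1 and 456 on tumor replicate 2, beside 113450 and 115410 on the normal arrays (adjusted p = 0.32). Klb, the co-receptor of FGF21, fell by 5.69 and Nrg4, a growth factor secreted by brown fat, fell by 5.29 (adjusted p = 0.0369 and 0.0288). The tumor signals of Klb also lay under the filter limit, and its difference was -7.85 with a pseudocount of 1 and -3.985 with 64. Fatty acid oxidation and lipid genes shifted downward with a median of -2.04 (-2.68 and -1.49 on tumor replicates 1 and 2, camera adjusted p = 0.000101, and adjusted p = 0.657 with an estimated correlation). Of 22 genes 2 fell, 1 rose and 19 did not pass, and adjusted over the list alone 9 were lower and 2 higher. Pdk4, which limits glucose oxidation, and Hadhb, of the mitochondrial trifunctional protein, fell by 5.52 and 2.85 (adjusted p = 0.0412 and 0.0425). Aldh1a2, which makes retinoic acid, rose by 2.67 (adjusted p = 0.0479). Oxidative phosphorylation genes shifted downward with a median of -1.11 (-1.50 and -0.75 on tumor replicates 1 and 2, camera adjusted p = 1.74e-11, and adjusted p = 0.657 with an estimated correlation), and 36 of 39 lay below both normal arrays on both tumor arrays. Of these 39 genes 0 passed and adjusted over the list alone 3 were lower, with Uqcrc1, of respiratory complex III, at -1.40 (adjusted p = 0.0714) and Ndufa4 at -1.11 (adjusted p = 0.101). The gene calls ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

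Smooth muscle genes, which mark the muscular wall of the ureter, also shifted downward as a list. The list had a median of -1.46 (-1.51 and -1.50 on tumor replicates 1 and 2, camera adjusted p = 1.48e-07, and adjusted p = 0.657 with an estimated correlation). Of 22 genes 2 fell and 20 did not pass, and adjusted over the list alone 13 were lower. Myh11, the smooth muscle myosin heavy chain, fell by 3.37 on the log2 scale (SE 0.25, n = 2 per group, limma adjusted p = 0.0402) and Mylk, the myosin light chain kinase, fell by 2.10 (SE 0.18, adjusted p = 0.0425). Hspb6 and Pgm5 had differences of -2.23 and -2.31 (adjusted p = 0.0526 each), and Acta2, the brightest member, one of -1.21. Skeletal muscle genes shifted downward with a median of -0.80 (camera adjusted p = 0.0271, and adjusted p = 0.657 with an estimated correlation), with 0 of 9 genes past the test and 3 lower when adjusted over the list alone. Without tumor replicate 1 or tumor replicate 2 that list missed the threshold, with adjusted p = 0.061 and 0.134. Tnnt1 and Ckm had differences of -2.95 and -2.27 (adjusted p = 0.104 and 0.0892). The other genes past the test with the largest falls were Sptssb, of sphingolipid synthesis (fell by 7.57, SE 0.33), the calmodulin-binding gene Pcp4 (fell by 6.98, SE 0.43), the ribonuclease Ang (fell by 6.20, SE 0.27), cardiac troponin Tnnt2 (fell by 5.51, SE 0.28), the paraoxonase Pon1 (fell by 5.49, SE 0.50), the glutamine transporter Slc1a5 (fell by 5.43, SE 0.22), the myosin light chain Myl1 (fell by 5.32, SE 0.57) and albumin, Alb (fell by 5.28, SE 0.57). Their adjusted p-values ran from 0.0288 to 0.0487. Ang was read from 1438936_s_at, and its other bright probe sets, 1438937_x_at and 1450717_at, gave -3.35 and -1.66. The tumor means of Pcp4, Ang, Tnnt2, Pon1 and Myl1 lay under the filter limit of 54.65, so the size and order of these falls depend on the pseudocount, and that of Myl1 was -6.20 with a pseudocount of 1, where its call ended (adjusted p = 0.0774), and -4.17 with 64. The gene calls ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.

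Kidney tubule genes had a median of -0.74, and -3.55 on tumor replicate 1 and 1.76 on tumor replicate 2. The list did not pass (camera adjusted p = 0.239), with 0 of 22 genes past the test and 1 lower when adjusted over the list alone. It passed downward without tumor replicate 2 (adjusted p = 2.64e-13) and upward without tumor replicate 1 (adjusted p = 6.65e-08). Kap, an androgen-regulated kidney protein and the brightest member, had a signal of 16792 and 41745 on the normal arrays, 101 on tumor replicate 1 and 52269 on tumor replicate 2. Miox, an inositol oxygenase of the proximal tubule, had a signal of 4199 and 3672 on the normal arrays, 3.34 on tumor replicate 1 and 9437 on tumor replicate 2. Cyp2e1, which fat and liver also express, had a difference of -2.91 (SE 0.41, n = 2 per group, limma adjusted p = 0.069).

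**Figure D3:**
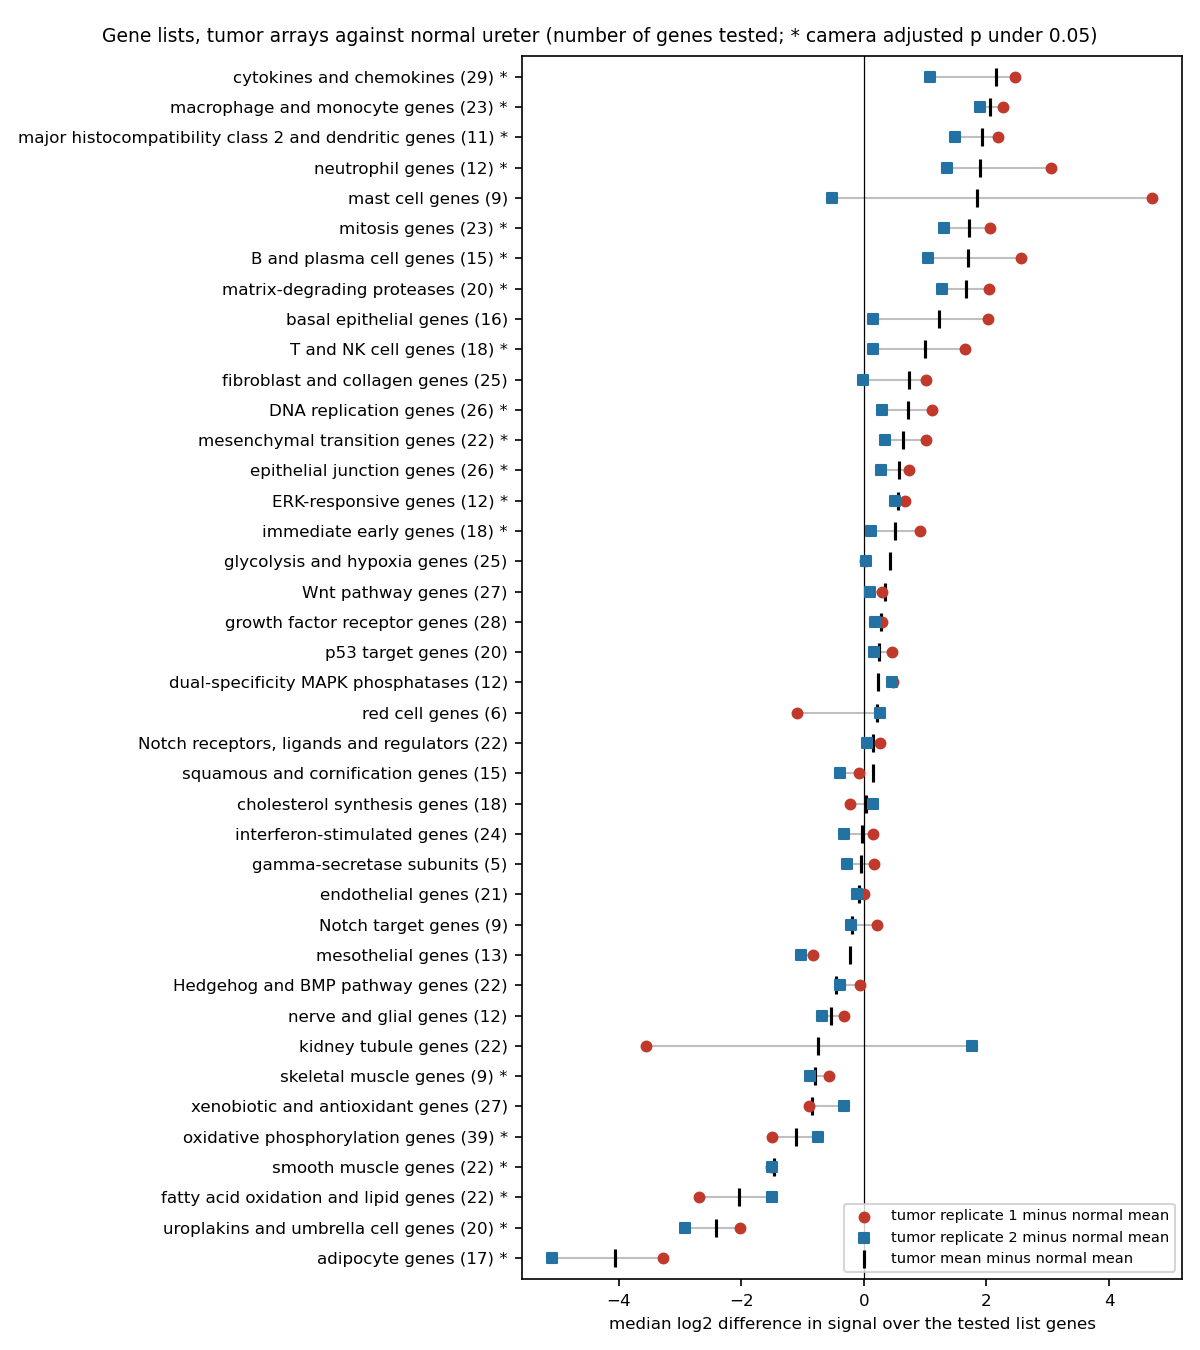
Median log2 difference in signal over the tested genes of each of the 40 gene lists. The horizontal axis is the median log2 difference from the normal mean, the black bar uses the tumor mean, and the red circle and blue square use tumor replicates 1 and 2. Numbers in parentheses are genes tested, and an asterisk marks a camera adjusted p under 0.05, with 19 lists marked. The 2 tumor arrays lay on opposite sides of 0 for kidney tubule (-3.55 and 1.76) and mast cell genes (4.70 and -0.52).

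Of the 40 lists tested 19 passed the camera test, 13 upward and 6 downward, and with an estimated correlation 0 passed. In the fry test 0 lists moved on balance in 1 direction, with a smallest adjusted p of 0.0929, and 33 lists held genes that changed in either direction, with a smallest adjusted p of 0.00121. The lists that did not pass included glycolysis and hypoxia genes (median 0.43, camera adjusted p = 0.882), where the glucose transporter Slc2a1 rose by 1.94 and the phosphofructokinase regulator Pfkfb3 fell by 2.41 (limma adjusted p = 0.0441 and 0.0425), 23 of 25 did not pass, and adjusted over the list alone 1 was higher and 3 lower. Wnt pathway genes had a median of 0.35 (adjusted p = 0.237), with the antagonist Dkk2 alone rising, by 2.37 (adjusted p = 0.044), 26 of 27 not passing, and 1 higher and 1 lower when adjusted over the list alone. The Wnt list passed without tumor replicate 2, with adjusted p = 0.0422. Hedgehog and BMP genes had a median of -0.46 (adjusted p = 0.398), with 0 of 22 past the test, 2 lower when adjusted over the list alone, and Bmp2 at -1.85 (adjusted p = 0.0568). Growth factor receptor genes had a median of 0.29 (adjusted p = 0.438), with 27 of 28 genes not past the test, Nrg4 lower, and 1 higher and 1 lower when adjusted over the list alone. Xenobiotic and antioxidant genes had a median of -0.84 (adjusted p = 0.105), with 1 of 27 past the test, the dioxin-induced Cyp1b1, which rose by 2.67 (adjusted p = 0.0441), and 1 higher and 2 lower when adjusted over the list alone. That list passed without normal replicate 1 and without tumor replicate 2, with adjusted p = 0.0355 and 0.00965. Interferon-stimulated genes had a median of -0.03 (adjusted p = 0.398) and endothelial genes one of -0.08 (adjusted p = 0.769), with 0 of 24 and 0 of 21 genes past the test over all genes and 0 when adjusted over the list alone. Cholesterol synthesis genes had a median of 0.03, a mean of -0.02 and a test that pointed down (adjusted p = 0.82), with 0 of 18 past the test and 2 higher and 2 lower when adjusted over the list alone. Red cell genes had a median of 0.21, a mean of -0.19 and a test that pointed down (adjusted p = 0.84), with 0 of 6 past the test over all genes or when adjusted over the list alone. Nerve and glial genes had a median of -0.54 (adjusted p = 0.233), with the neuronal hydrolase Uchl1 alone falling, by 3.40 (adjusted p = 0.0425), 11 of 12 not passing, and 4 lower and 1 higher when adjusted over the list alone. Mesothelial genes had a median of -0.23 (adjusted p = 0.235), with 12 of 13 not past the test, Upk1b lower, and 2 lower and 1 higher when adjusted over the list alone. Of the male accessory gland genes 4 were tested, too few for a list test, and 0 passed. The calls of single genes ended without normal replicate 1 or normal replicate 2, each of which left 0 genes.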

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

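These values come from data outside the comparisons of genes, and both were chosen after the arrays were examined. The 3 control probe sets for 18S ribosomal RNA, which are not genes of the comparison, had a mean log2 difference of 2.56 between tumor and normal arrays, 5.89-fold. The signal of the control for the 5' part was 2094 and 3305 on the normal arrays, and 25810 and 18520 on the tumor arrays. No explanation of this difference was tested.

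Among 27020 probe sets tested without regard to gene names, 4071 had no single gene name here, and of these 24 were higher and 53 lower in the tumors at a limma adjusted p under 0.05. Those with the largest rise were 9.27, 8.51 and 8.47 higher on the log2 scale (adjusted p = 0.028, 0.0241 and 0.0323). The last of these is shared by Iglc1 and Iglv1, which encode immunoglobulin lambda chains.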

How the results depend on the processing

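The alternatives reported here were all chosen before the data were examined. None of the 56 named genes past the test reversed in the alternatives that refit single genes, which every probe set and the 2-fold rule do not. A second bright probe set of 1 of them, Itgb6, pointed the other way (-0.345). Their calls depended on the setting. All 56 were kept without tumor replicate 1 and without tumor replicate 2, 55 with a pseudocount of 64 and with median-centring, 53 with the robust trend, 52 of 55 with a pseudocount of 1, 52 of 52 with the 60th percentile filter, 52 under quantile normalization, 43 with no filter, 35 of 54 with the mean of probe sets, 2 without the intensity trend and 0 without normal replicate 1, without normal replicate 2 or with the replicate block. Calls ended for Igk, Pon1 and Myl1 with a pseudocount of 1, Alb with 64, Tagln2, Myl1, Alb and Itgb6 under quantile normalization, Itgb6 with median-centring, and Iglv1, Tagln2 and Alb with the robust trend. With no filter they ended for Gpr176, Cldn3, Trem2, Tagln2, Myl1, Alb, Csf1r, Adamts1, Cxcl1, Aldh1a2, Egr2, Itgb6 and Slc2a1. With the mean of probe sets they ended for Iglv1, Igk, Inhba, Frzb, Igkv9-120, Tagln2, Myl1, Alb, Ms4a7, Adamts1, Cxcl1, Myh11, Mylk, Pnpla2, Hadhb, Itgb6, Slc2a1, Pfkfb3 and Cyp1b1. Without the intensity trend Igha and Ucp1 alone were kept. With 1 normal array left the variance came from the tumor pair alone, and with 1 tumor array left it came from the closer normal pair, so the calls rest on the spread of the pair that remains. The cause of the other changes was not tested. Signal over background limits dim genes, whose changes shrink with the pseudocount.

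The count of 187 genes (64 higher, 123 lower) was 117 (33 higher) with the mean of probe sets, 287 (196 lower) with every probe set, 2 (1 higher, 1 lower) with no intensity trend, and 1880 (901 higher, 979 lower) with a rule of 2-fold at an unadjusted p under 0.05. The counts under the other alternatives of scaling, pseudocount, filter and robust trend lay between 140 and 243. Leaving out each array in turn gave 0 to 5502 genes, with 0 to 2749 higher and 0 to 2753 lower. Without the intensity trend 2739 genes had an unadjusted p under 0.05. Of the 3 splits of the 4 arrays into groups of 2, 1 split, the real one, gave as many as 187 genes and the highest other gave 0, and 3 splits are too few for a share under 0.05.

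With the replicate number as a replicate block limma called 0 genes (0 higher, 0 lower), with 2253 at an unadjusted p under 0.05, and 22 lists passed. The correlation between groups of the differences between replicates 1 and 2, across genes, was 0.0391, which gave no sign of a pairing by number. It cannot exclude a smaller shared effect, since 1111 genes differed at least 4-fold between the tumor arrays and 49 between the normal arrays.

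The 19 lists past the camera test numbered 17 to 22 under the alternatives of scaling, pseudocount, filter, probe sets, trend and block, 14 to 24 with each array left out in turn, 0 with an estimated correlation and 0 with fry. No list past the test reversed under any alternative. Results that reversed were all short of the threshold before, and the cause was not tested. Under quantile normalization these were Dusp8 (0.094) and Dusp9 (0.0409). Under median-centring it was the squamous list (0.0514). With no filter they were the squamous list (0.246) and the Notch target list (-0.2015), whose tests turned while the medians kept their signs. With the 60th percentile filter they were the Notch target list (0.271) and the glycolysis list (0.464). With the mean of probe sets they were the Notch receptor list (-0.0724), the gamma-secretase list (-0.1099), the cholesterol list (0.05501), Dusp9 (0.083), Ncstn (-0.114) and Notch2 (-0.220). With every probe set they were the gamma-secretase list (-0.1099), the Notch target list (-0.07891), the cholesterol list (0.0661) and the Hedgehog and BMP list (0.0405). With fry they were the glycolysis list (0.432) and the growth factor receptor list (0.288), whose medians are the same and whose test direction turned.

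With each array left out in turn, the lists whose test reversed had medians from -0.0159 to 0.273 (Notch receptors), -0.278 to 0.162 (gamma-secretase), -0.246 to 0.219 (Notch targets), 0.142 to 2.028 (basal), -0.381 to 0.218 (squamous), -0.0173 to 1.014 (fibroblast), -0.515 to 4.702 (mast cell), -3.547 to 1.756 (kidney), -1.094 to 0.276 (red cell), 0.0214 to 0.454 (glycolysis) and -0.224 to 0.281 (cholesterol). The genes that reversed had differences from -0.490 to 0.261 (Dusp1), -0.0134 to 1.318 (Dusp2), -0.305 to 0.651 (Dusp3), -0.666 to 0.464 (Dusp8), -0.771 to 0.454 (Dusp9), -0.844 to 1.441 (Dusp10), -0.573 to 0.293 (Hes1), -0.202 to 0.170 (Jag1), -0.732 to 0.0512 (Notch1), -0.604 to 0.226 (Notch3), -0.382 to 0.162 (Psenen), -0.439 to 7.333 (Fcer1a), -0.992 to 6.491 (Gzma), -7.827 to 0.981 (Kap), -7.671 to 1.262 (Miox), -1.436 to 0.0875 (Krt7) and -1.701 to 0.189 (Dcn). Ncstn and Notch2 kept their sign, from 0.00477 to 0.592 and from 0.291 to 1.014, as did the Hedgehog and BMP list (-0.523 to -0.0562) and the growth factor receptor list (0.181 to 0.333).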

Other observations

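Apart from the genes that moved on both tumor arrays, each tumor array held a set of very bright transcripts of its own. The genes in this paragraph and the next, other than Mcpt1, Mcpt2 and Lcn2, were chosen after their values were seen. Siglecf, Epx, Kdm5d and Uty lay under the filter and were not tested, and none of the others passed the limma test. A gene that is high on 1 tumor array alone has no replicate. On tumor replicate 1, 48 tested genes were over 16-fold higher than on the other 3 arrays, against 13 on tumor replicate 2 and 0 on each normal array. The mast cell proteases Mcpt1 and Mcpt2 reached signals of 38867 and 52197 on tumor replicate 1 and stayed at 33.7 or less elsewhere. Chil4, a chitinase-like protein of type 2 inflammation, was at 85852, with 208 on tumor replicate 2, and Clca1, a secreted protein of goblet cells, was at 25377. The eosinophil genes Siglecf and Epx were at 1131 and 834 on tumor replicate 1, with 26.5 and 5.35 on tumor replicate 2. Keratins of basal and squamous cells stood out there too, with Krt14 at 16715 and Krt6a at 8342, beside 1088 and 76.2 on tumor replicate 2, and Krt5 at 15780, beside 628 on tumor replicate 2 and 3415 and 5518 on the normal arrays. The epithelial transcription factor Sox2 was at 6582 on tumor replicate 1 and at 28.6 or less elsewhere, while Trp63 was at 10167 on tumor replicate 1 and 440 on tumor replicate 2, beside 2446 and 3847 on the normal arrays.

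On tumor replicate 2 several transcripts of the nephron were bright. Umod, a urinary protein made by the nephron, was at 57258, beside 1268 on tumor replicate 1 and 4997 and 9982 on the normal arrays. The sodium transporter Slc12a1 was at 23388, with 1348 and 2615 on the normal arrays, the potassium channel Kcnj1 at 7397, with 270 and 576, and the intercalated cell channel Aqp6 at 3788, with 51.3 and 67.0. Havcr1, a marker of tubule injury, was at 3218, with 2.25 and 8.23 on the normal arrays, and Lcn2 was at 18261, beside 917 on tumor replicate 1 and 90.8 and 80.6 on the normal arrays. Ighg3 was also raised on both tumor arrays, at 29745 on tumor replicate 2 and 4877 on tumor replicate 1, where the normal arrays gave 61.9 and 60.8. Xist, transcribed from the inactive X chromosome, was at 24998, 25925 and 20566 on the normal arrays and tumor replicate 1, and at 41.9 on tumor replicate 2. The Y-linked genes Eif2s3y and Kdm5d were at 1708 and 514 on tumor replicate 2 and at 23.2 or less on the other arrays. Uty, also Y-linked, was dimmer and less clear, at 121 on tumor replicate 2, 1.64 on tumor replicate 1 and 32.6 and 65.8 on the normal arrays. The sex of the mice is not given in the sources used here. By Xist, Eif2s3y and Kdm5d, tumor replicate 2 read as male and the other arrays as female. Sex thus differed within the tumor pair but not within the normal pair, and it was not modelled in the comparison of tumor with normal.

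The tests in the next 3 paragraphs were chosen after the result was seen, except the test for a normal sample under a tumor label. The fall of fat cell genes was set against scaling and against fat in the normal pieces. Under quantile normalization the list median stayed at -4.034. The arrays already shared a trimmed mean of 500 and had close 90th percentiles, from 1618 to 1675, so that step could hardly have moved the list. The median difference over all genes tested was 0.03, which argues against a factor common to all genes of an array. Of 17 measured fat cell genes, 15 lay above the 90th percentile of signal on both normal arrays and 4 on both tumor arrays, with Adipoq at 81675 and 84064 on the normal arrays, 9631 on tumor replicate 1 and 6.28 on tumor replicate 2, and none of the 17 is on another list here. Fat cell transcripts were thus abundant in the normal pieces, although the isolation of epithelium in the labels would remove fat. These levels restate the pattern, so they do not give the reason for the fall. On tumor replicate 1, 7 of the 17 lay above that percentile, and on tumor replicate 2, 4 did. Fat cell transcripts were thus not confined to the normal pieces. A larger amount of fat carried along with the normal pieces and a loss of fat in the mice with tumors cannot be told apart.

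The kidney genes of tumor replicate 2 were set against kidney tissue and a wrong label. Of 22 measured kidney genes, 20 lay above the 90th percentile of signal on tumor replicate 2, with Umod at 57258 and Kap at 52269, against 10 on both normal arrays and 3 on tumor replicate 1, and 1 of the 22 is on another list. The genes at least 4-fold above both normal arrays on tumor replicate 1 were taken. If a sample like the 2 normal ones stood under the tumor label, about 33.33% of them would lie above both normal arrays on tumor replicate 2. The share was 82.0% of 628 genes (exact 95% interval 78.77 to 84.93, over genes, which are not independent). This argues against a sample like the 2 normal ones. It cannot exclude a normal piece of other sex or tissue content, for which 33.33% need not hold. Pearson's r across genes was 0.824 and 0.827 between tumor replicate 2 and the normal arrays, and 0.786 between the tumor arrays. The levels of kidney genes on tumor replicate 2 restate the pattern. Kidney tissue in the piece and a change within the tumor therefore cannot be told apart there. The isolation of ureter epithelium in the labels would remove kidney tissue. Yet 10 kidney genes were bright on both normal arrays, which a change within a tumor does not cover. Tumor replicate 2 also read as male by Xist and Y-linked genes, and the part of sex in androgen-regulated genes such as Kap was not tested.

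The lower umbrella cell genes were set against a smaller share of urothelium, which would lower basal genes alike. On tumor replicate 1 the basal list had a median of 2.03 (quartiles 1.72 and 3.53) while the umbrella cell list had -2.02. This argues against a like fall of both lists there. It cannot exclude less urothelium beside other epithelium rich in basal genes, as the squamous keratins Krt4 and Krt6a were at 16802 and 8342. Shh, made by basal urothelial cells, was at 771 there, beside 8592 and 13234 on the normal arrays. On tumor replicate 2 the basal list had a median of 0.142 (quartiles -1.03 and 0.964) and the umbrella cell list -2.91, and with Krt5 at 628 and Itga6 at 4061 its genes went both ways, so that less urothelium and lost differentiation cannot be told apart. In these lists 3 of the umbrella cell genes and 2 of the basal genes are also on another list. A change in the differentiation of the tumor epithelium, and the deletion of Ncstn as its cause, were not tested and stay open.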
